A study of Oryza sativa with 4 samples.

How the data were processed

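Transcripts of rice calli were measured on 4 dual-colour Agilent oligonucleotide arrays, 1 for each of 4 transgenic calli, which carried a DEX-inducible (GVG) construct for MYB30, MYB55 or MYB110 or an empty vector. Per the labels, the Cy3 channel of every array held RNA of DEX-treated calli and the Cy5 channel RNA of ethanol-treated calli of the same line. No array had its dyes swapped, so a dye bias of single probes stays within each ratio. All 4 arrays lay on 1 slide, so the slide could not be used as a block.

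The deposited scanner files give the intensity of each spot as a mean signal and a local background median for each channel, extracted with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. The same files hold processed signals, which the software had background-subtracted, detrended and dye-normalized within each array, per the file headers. They also hold the log10 ratio of Cy5 over Cy3 with a log10 error from the software's error model, per the file headers. A deposited series table gives 1 log2 value per spot and array. Set against the scanner values, matched on spot number, each of its columns equalled the log2 ratio of the Cy3 over the Cy5 processed signal (Pearson r = 1.00 across 45151 spots, largest gap 0.00), so scale and direction were settled and no further centring had been applied. The column medians were 0.07 for MYB30, -0.01 for MYB55, 0.07 for MYB110 and 0.06 for the vector. The software's own ratio was set to exactly 0 for 6487, 5274, 6052 and 6178 spots of these arrays in that order, and matched the table at all other spots.

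From the mean signals, the background was corrected with normexp and an offset of 50 over all spots, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 1417 control spots and spots with a non-uniformity or population outlier flag (75 to 102 per array) were left out, and spots of one probe were averaged. Ratios were turned to DEX over ethanol. Of 43734 other spots, 42124 name a rice locus in the probe name, giving 29690 loci. The 1610 spots without a locus entered no comparison. A locus with several probes, as 7801 had, was represented by its probe with the highest mean intensity over the arrays. Locus names and descriptions are those of the array design and can be old. The reference table given here (assembly GCF_034140825.1) does not use these locus names and was not used, and no genome was used. In 268 cases one probe sequence was assigned to more than 1 locus.

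There were no replicates and so no statistical test and no p-value. A gene was called higher or lower in an MYB array when its log2 ratio and its difference from the ratio of the vector array both reached 1 in size in one direction, and its probe was well above background in the brighter channel. For the vector array the own ratio alone was used. Genes well above background in neither channel count as not measured. Errors written after ± are the technical error that the software gave for its own ratio, in log2 units, combined in quadrature for a difference. They were not recomputed for the normalized ratios beside which they stand. They hold no biological variation. A channel not well above background gives only a bound, written as at least N-fold. It sets the bright channel, after loess and Aquantile scaling, against the higher of the dim spot's own signal and the lowest signal well above background in that channel, and is open to dye bias.

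The 20 gene lists were fixed before the data were examined, by locus or by words in the gene descriptions. They cover shikimate and phenylalanine synthesis, phenylpropanoid entry, monolignol and hydroxycinnamate steps, flavonoids, tryptophan and aromatic amines, the methyl donor cycle, diterpenoid phytoalexins, pathogenesis-related proteins, jasmonate, WRKY factors, MYB factors, glutathione transferases with glucosyltransferases, peroxidases with laccases, heat shock, ethanol and low oxygen, amylase with amide amino acids, histones with cell division, ribosomal proteins, photosynthesis, and storage with seed tissue. The last groups also stand for dividing, greening and seed-like cells that callus could hold. Each list's median was placed as a percentile among 10000 random lists of the same size, matched on intensity in 20 bins. Word matching has side effects: 7 loci of the phenylpropanoid entry list also fall in the monolignol list, because 4-coumarate-CoA ligases carry a coumaroyl synonym. The pathogenesis-related list takes in transcription factors described as pathogenesis-related with an ERF domain. It misses JIOsPR10, which the array describes as pathogen-related. The amylase and amide list takes beta-amylases but not alpha-amylases, with glutamine synthetases, glutamate decarboxylases and glutamine amidotransferases.

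Named genes follow a rule fixed at the same time. It takes the 3 MYB genes, the 10 highest and 5 lowest described genes of each MYB array, and up to 4 called members of each list, or the 2 with the largest difference, as values, where none was called. It adds 10 genes called in all 3 MYB arrays, 5 highest and 5 lowest genes of the vector array, and up to 4 genes called in opposite directions.

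Because the 3 MYB arrays share the vector array, overlaps were set beside 1000 simulated sets of arrays without an MYB effect. Each simulated array held the vector ratios permuted within 20 intensity bins, so it kept the whole spread of the vector array. The permutation removed any DEX response or dye bias of a gene that a real array could share with the vector array. Numbers of calls in real and simulated arrays are therefore not directly comparable. Overlaps of independent lists were also computed. The single vector array could not be split.

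The procedure was tested on a simulated array with 200 changed probes, set against a simulated vector array of 43734 probes. The rule called 68.0% of the probes raised by 1.5 log2 units, 54.0% of those lowered by 1.5, all 50 raised by 3 and 94.0% of those lowered by 3. Mean ratios came back as 1.22, -1.13, 2.62 and -2.15, so the procedure shrank ratios, and more so for lowered probes. Which step did so was not tested. Of 43534 unchanged simulated probes 2 were called. The simulated arrays held only technical noise and an intensity-dependent dye bias, with no biological change. The changed probes were drawn from those well above background in both channels of the vector array. The test therefore gives no rate of false calls for the real arrays.

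Alternatives fixed in advance changed the background correction, the signals, the normalization, the filter on dim probes, the choice of probe, the outlier spots, the use of the vector array and the threshold. A further 2 were added after the data were seen. They limited calls to genes measured in the vector array and put the bound in place of a ratio with 1 dim channel.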

Results

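Callus of japonica rice (Oryza sativa), a mass of undifferentiated cells kept in culture, was treated with the steroid dexamethasone (DEX) or with ethanol, its solvent. The calli carried a GVG construct, a steroid-activated expression system, for one of 3 MYB transcription factors (MYB30, MYB55 or MYB110), or an empty vector. RNA was taken 4 h after treatment, following 18 h in suspension. The labels give 10 mM DEX and the same value for its stock solution, so the working concentration is not settled. Each line was measured on 1 array with DEX and ethanol RNA side by side, and there were no replicates, so the number of arrays limits the precision. Between 69.7% and 71.6% of spots were well above background in the DEX channel and 75.2% to 76.9% in the ethanol channel, and no spot was saturated. Measured genes numbered 22619 in the array labelled MYB30, 23339 in MYB55, 23179 in MYB110 and 23030 in the vector array. Replicate spots of one probe differed by a median SD of 0.03 to 0.04 log2 units within an array. The question is which transcripts change after induction of each MYB gene.

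The probes of the 3 MYB genes did not single out the array of their own construct. The locus taken as MYB30, Os02g0624300, had a log2 ratio of DEX over ethanol of 0.27 ± 0.28 in the array labelled MYB30 and 1.28 ± 0.29 in the vector array. For MYB55, Os05g0553400, the ratio was 1.80 ± 0.26 in its own array, but also 2.15 ± 0.30 in MYB30, 1.32 ± 0.24 in MYB110 and 2.17 ± 0.30 in the vector array. For MYB110, Os10g0478300, it was -1.52 ± 0.27 in its own array and 1.77 ± 0.27 in the vector array. A second probe of Os10g0478300 gave -1.21 and 1.19. The pairing of loci with construct names comes from background knowledge, since the array descriptions do not use these names. Each of the 4 probes has at least 1 forward frame without a stop codon, so their sequence does not tell whether they can detect a construct's transcript. A probe outside the transgene checks nothing. Arrays are therefore named by label throughout, and every direction rests on the labels.

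In the vector array, DEX went with large changes although no MYB gene was on the construct. The highest described genes were alpha-amylase 3A (Os09g0457400, 4.22 ± 0.45 log2 units), a CBF-like gene (Os09g0522000, 3.99), an auxin efflux carrier gene (Os01g0802700, 3.77), a LysM domain gene (Os10g0524300, 3.75) and a strictosidine synthase family gene (Os08g0442200, 3.71). The lowest were a PLAT domain lipase gene (Os10g0361000, -4.83), an AUX1-like gene of auxin uptake (Os10g0147400, -3.91), S-adenosylmethionine decarboxylase (Os09g0424300, -3.44), a cystinosin homolog (Os12g0278700, -2.99) and a thionin (Os02g0629800, -2.95). A second probe of Os12g0278700 had only -0.72, short of the threshold. In all, 1337 genes were higher and 679 lower. Among the fixed lists, 15 of 50 measured WRKY factors were higher and 1 lower (median 0.45, percentile 100 of random lists). Of 152 glutathione transferase and glucosyltransferase genes 29 were higher and none lower (median 0.28). Heat shock genes had 28 of 191 higher and 4 lower, and jasmonate genes 6 of 24 higher and none lower (median 0.35). Histone and cell division genes had 6 of 52 higher (median 0.31). Ribosomal protein genes lay the other way, with 15 of 299 lower, none higher and a median of -0.42, below every random list. Phenylpropanoid entry genes had 3 of 16 higher (median 0.25, percentile 97.5). With the software's processed signals the vector array had 2014 higher and 2379 lower genes, so that 45.8% of calls were higher against 66.3%, and 25.8% with median centring.

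In the array labelled MYB30, 10 of 17 measured genes at the entry from phenylalanine to lignin and related phenolics were called higher with DEX. 4-Coumarate-CoA ligase (4CL, Os02g0177600), which activates hydroxycinnamic acids, exceeded the vector array by 5.78 ± 0.69 log2 units. Phenylalanine ammonia-lyase (PAL, Os05g0427400), which turns phenylalanine into cinnamic acid, was at least 61.0-fold higher with DEX, its ethanol channel being not well above background. Caffeoyl-CoA O-methyltransferase (Os08g0498100) and caffeic acid O-methyltransferase (Os08g0157500), which methylate lignin precursors, exceeded the vector array by 4.17 ± 0.46 and 4.15 ± 0.40. The second had an own ratio of 2.41 and a vector ratio of -1.74. In total 409 genes were higher and 133 lower.

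None of the 17 phenylpropanoid entry genes was lower in the array labelled MYB30, and the list had a median difference of 1.82 above every random list. The median own ratio was 2.00, or 1.71 with dim channels at their bound. By its brightest probe a second PAL gene (Os02g0627100) was at least 14.6-fold higher, but its other probe had a ratio of 0.31 with a dim ethanol channel, short of the threshold. A second 4CL gene (Os08g0448000) differed by 2.86 ± 0.49. Requiring both channels above background leaves 6 of these calls. Shikimate and phenylalanine synthesis genes, which supply phenylalanine, had 9 of 24 higher and none lower (median 0.79, above every random list). They included shikimate kinase (Os04g0640600, 3.21 ± 0.42), chorismate mutase (Os01g0764400, 2.89) and DAHP synthase (Os07g0622200, 2.71). Prephenate dehydratase (Os04g0406600), dim in the DEX channel of the vector array, had an own ratio of 2.67. Monolignol genes, of later steps towards lignin, had 5 of 22 higher (median 0.53), or 3 of 18 (median 0.49) without the entry list's members. Methyl donor genes had 6 of 14 higher (median 1.12, above every random list, against -0.35 for the vector ratio), among them methionine synthase (Os12g0623900, 2.17 ± 0.33) and adenosylhomocysteinase (Os11g0455500, 2.16 ± 0.33). Tyrosine decarboxylase (Os07g0437500, 1.75) was the single gene called higher among 21 tryptophan and amine genes, on 1 probe, its other probe being dim in both channels.

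Other high genes in this array were an endo-1,4-beta-glucanase of cell walls (Os01g0312800, 4.98 ± 0.46), a B3 family factor (Os01g0234100, 4.43), a PR10 protein (JIOsPR10, Os03g0300400, 4.29, with an own ratio of 4.35 against 1.12 on its second probe, which is dim in the ethanol channel), a fasciclin domain gene (Os05g0563600, 4.13) and the cystinosin homolog Os12g0278700 (4.52). The value of the last rests on the vector array, since its own ratio was 1.53 and the vector's -2.99. Its second probe did not pass the rule (0.20 and -0.72). The endo-1,4-beta-glucanase also had a low vector ratio, of -1.92, beside an own ratio of 3.065. The lowest were a cytochrome P450 gene (Os10g0525000, -3.65), gibberellin 2-oxidase (Os01g0757200, -3.33), which inactivates gibberellins, a gene described as Blind (Os01g0685400, -3.13), a subtilisin propeptide gene (Os07g0438600, -2.96) and peroxidase P7 (Os06g0547400, -2.93). All 5 had vector ratios of 1.49 or more. The gibberellin 2-oxidase gene Os01g0757200 had an own ratio of -1.26 on its brightest probe. Of its 4 other probes, 3 fell short of the threshold with own ratios of -0.98, -0.77 and -0.52, and 1 was dim in both channels. Among MYB factors 6 of 125 were higher and 4 lower (median -0.19, own ratio -0.07). MYB8 (Os04g0594100) was at least 9.33-fold higher, and OSMYB4 (Os01g0695900) differed by 2.01. No WRKY factor of 45 was called (median -0.45, own ratio -0.05). Peroxidases and laccases had 5 of 59 higher and 4 lower, and pathogenesis-related genes 2 of 92 higher and 1 lower (median -0.26, own ratio -0.14). Single calls in each direction came from 26 flavonoid, 190 heat shock and 34 photosynthesis genes. Jasmonate genes had 1 of 23 lower (median -0.62, own ratio -0.09, vector ratio 0.35), transferases 4 of 150 higher and 1 lower (median -0.33, own ratio -0.03), ethanol and low oxygen genes 2 of 40 higher (median -0.28, own ratio -0.09), and ribosomal protein genes 4 of 298 higher (median 0.70, own ratio 0.30). No gene of the histone, amylase and amide, or storage lists was called, and the storage list had a median of -0.41 (own ratio -0.19). Of 2 measured diterpenoid phytoalexin genes 1 was higher, Os12g0240900. The array describes it as a caffeic acid methyltransferase, so the monolignol list holds it too, and its place in this list, as a naringenin methyltransferase, is background knowledge. With the software's processed signals 697 genes were higher and 494 lower, so the share of higher calls was 58.5% against 75.5%, and 47.8% with median centring. Simulated arrays without an MYB effect gave a mean of 996.8 higher and 479.9 lower calls. They kept the spread of the vector array, with a robust SD of 0.44 against 0.31 here, and no gene's DEX response. The comparison therefore cannot tell whether the 409 and 133 calls set this array apart.

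In the array labelled MYB55, 13 of 20 measured phenylpropanoid entry genes and 11 of 24 genes of phenylalanine supply were called higher, and more genes passed the rule than in the other MYB arrays. Its ratios also spread more, with a robust SD of 0.43 against 0.31 in MYB30 and 0.33 in MYB110. The fixed threshold takes no account of this spread. JIOsPR10 (Os03g0300400), a pathogenesis-related protein, exceeded the vector array by 8.14 ± 0.85 log2 units. Its second probe, dim in both channels of the vector array and in the ethanol channel here, had a fitted own ratio of 5.99 against 8.20. PAL genes Os05g0427400, Os02g0627100 and Os04g0518100 exceeded it by 8.09 ± 0.88, 7.70 ± 0.83 and 6.25 ± 0.68, and the second probes of the last 2 had lower own ratios of 2.89 and 3.07. In total 1444 genes were higher and 221 lower.

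Phenylpropanoid entry genes had 13 of 20 higher and none lower in the array labelled MYB55, with a median of 2.36 above every random list. 4CL (Os02g0177600) differed by 6.10 ± 0.66, and PAL2 (Os04g0518400), dim in the DEX channel of the vector array, had an own ratio of 6.30 ± 0.72. Shikimate and phenylalanine synthesis genes had 11 of 24 higher and none lower (median 0.72, above every random list). They included chorismate mutase (Os01g0764400, 4.42 ± 0.49), DAHP synthase (Os03g0389700, 4.37, with a vector ratio of 1.34) and shikimate kinase (Os04g0640600, 4.34). Monolignol genes had 9 of 25 higher (median 0.79), or 6 of 19 (median 0.47) without the entry list's members, and methyl donor genes 8 of 14 (median 1.83). Adenosylhomocysteinase (Os11g0455500) differed by 3.22 ± 0.37, methylenetetrahydrofolate reductase (Os03g0815200), which supplies the methyl group of methionine, by 3.19, and adenosine kinase (Os02g0625500) by 2.41. Tryptophan and amine genes had 5 of 21 higher (median 0.37, percentile 99.4), with indole-3-glycerol phosphate synthase genes Os08g0320400 (3.03) and Os09g0255400 (2.90, its other probe being dim in both channels). Among 30 flavonoid genes 6 were higher, with chalcone-flavanone isomerase family gene Os11g0116300 at 4.07 ± 0.51.

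Peroxidases and laccases had 14 of 81 higher and 1 lower in this array (median 0.40, above every random list). The size of this median depended on the scaling, from 0.142 to 0.525. A haem peroxidase (Os05g0499400) differed by 3.94 ± 0.42 and peroxidase 52 (Os01g0205900) by 3.12. Anionic peroxidase (Os04g0689000), dim in both channels of the vector array, had an own ratio of 5.49 ± 0.57. Genes of the pathogenesis-related list, which holds some ERF factors but not JIOsPR10, had 16 of 104 higher and 1 lower. They included a thaumatin-like gene (Os03g0243900, 2.87), but their median of 0.07 changed sign under 3 of 6 other scalings. MYB factors had 12 of 124 higher and 4 lower (median -0.10, own ratio 0.07), the higher ones including Os08g0549000 (5.36 ± 0.65), Os05g0429900 (4.40) and Os11g0180900, with an own ratio of 6.16 and a dim DEX channel in the vector array. Further high genes were a fasciclin domain gene (Os01g0668100, 6.44) and an aminomethyltransferase of glycine cleavage (Os04g0623800, 6.21), and phospholipase D2 (Os06g0604300) was at least 68.5-fold higher. The lowest were a homeobox gene (Os01g0840300, -3.30), a MYB-related gene (Os03g0315400, -3.25), a RING finger gene (Os01g0212700, -3.23), a family 29 glycosyltransferase (Os04g0506800, -3.12, with 1 of its other probes short of the threshold at an own ratio of -0.92) and the ethylene response factor OsERF3 (Os02g0655200, -3.08). Their vector ratios in this order were 0.84, 2.02, 1.57, 2.11 and 1.99, so that the own ratios of the last 2 were -1.02 and -1.09. Jasmonate genes had 3 of 26 higher, with lipoxygenase Os03g0700400 at 1.97, and WRKY factors 2 of 57 (median -0.16, own ratio 0.07), with WRKY69 (Os08g0386200) at 1.93, though its second probe did not pass the rule. Transferases had 9 of 153 higher and 6 lower, heat shock genes 8 of 187 and 1, ethanol and low oxygen genes 3 of 44 and 1. Against these counts their medians were low among random lists, at -0.25, -0.23 and -0.28, while their own ratios were -0.03, -0.04 and 0.004. Photosynthesis genes had 5 of 33 higher and amylase and amide genes 1 of 17, both with medians that changed sign under 4 of 6 other scalings. Ribosomal protein genes had 2 of 300 higher, with a median difference of 0.24 but an own ratio of -0.21. Histone and storage genes had 1 of 51 and 1 of 28 lower (medians -0.45 and -0.43, own ratios -0.14 and -0.22), and 1 of 6 diterpenoid phytoalexin genes was higher. With the software's processed signals 63.4% of calls were higher against 86.7%, with 1062 genes lower, and 59.6% with median centring. The 221 lower calls are fewer than the 479.9 of the simulated arrays, and the 1444 higher calls more than their 996.8. Since the simulated arrays kept no gene's DEX response, this decides nothing.

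In the array labelled MYB110, 12 of 17 measured phenylpropanoid entry genes and 10 of 25 genes of phenylalanine supply were called higher. Of the 537 lower genes 270 were called higher in the vector array, as were 16 of 133 in MYB30 and 23 of 221 in MYB55. A high vector ratio helps a lower gene pass the rule, and these counts rest on the labels. JIOsPR10 (Os03g0300400) exceeded the vector array by 6.46 ± 0.69 log2 units, with own ratios of 6.52 and, on its second probe, 4.51. PAL (Os05g0427400) exceeded it by 6.19 ± 0.71 and 4CL (Os02g0177600) by 5.57 ± 0.62. Alpha-amylase 3A (Os09g0457400), a starch-degrading enzyme, was at least 8.02-fold lower with DEX within this array by its brightest probe. Its other probes, also dim in the DEX channel, had fitted own ratios of -2.88 and -1.18. In total 616 genes were higher and 537 lower.

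Phenylpropanoid entry genes had 12 of 17 higher and 1 lower in the array labelled MYB110 (median 2.43, above every random list). PAL gene Os02g0627100 differed by 5.86 ± 0.67, with a lower own ratio of 1.88 on its second probe, and PAL2 (Os04g0518400) was at least 11.6-fold higher. Shikimate and phenylalanine synthesis genes had 10 of 25 higher (median 0.90, above every random list), with shikimate kinase (Os04g0640600) at 3.63 ± 0.44, DAHP synthase (Os07g0622200) at 3.50 and chorismate mutase (Os01g0764400) at 3.32. Monolignol genes had 7 of 25 higher (median 0.40), or 5 of 21 (median 0.14) without the entry list's members. Methyl donor genes had 9 of 14 higher and 1 lower (median 1.77), led in difference by homocysteine methyltransferase (Os03g0221200, 3.80 ± 0.39). Its own ratio was 2.20 and its vector ratio -1.61. Tryptophan and amine genes had 7 of 22 higher (median 0.36, percentile 98.9), with an anthranilate phosphoribosyltransferase-like gene (Os05g0429700) at 1.89. Other high genes were a GDSL lipase (Os02g0617400, 4.54 ± 0.57), the endo-1,4-beta-glucanase Os01g0312800 (4.44) and MipE (Os04g0233400, 4.25). The glucanase and MipE had own ratios of 2.52 and 2.80, beside vector ratios of -1.92 and -1.45. The MYB gene Os11g0180900 and a CD9 antigen family gene (Os08g0443800), each dim in the DEX channel of the vector array, had own ratios of 4.46 and 3.77.

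Glutathione transferases and glucosyltransferases had 10 of 156 lower and 1 higher in this array (median -0.40, own ratio -0.20). GST TSI-1 (Os10g0527400) of this list differed by -4.86. Tau class GST3 (Os10g0525600), whose description the list's words miss, differed by -5.13 ± 0.46, with a vector ratio of 3.29. Heat shock genes had 14 of 190 lower and 4 higher, and the list median of -0.09 became 0.06 with median centring. Heat shock factor 1 (Os05g0530400) differed by -4.50 ± 0.47, with an own ratio of -1.34 and a vector ratio of 3.165. Of its other probes 2 fell short with own ratios of -0.64 and -0.72, and differed from the vector array by -2.30 and -2.41. Histone and cell division genes had 11 of 52 lower and none higher (median -0.54, own ratio -0.39, vector ratio 0.31), with histone H4 (Os03g0119900) at -3.52 ± 0.37 and histone H3 (Os01g0866200) at -2.15. Pathogenesis-related genes had 9 lower and 3 higher (median -0.18, own ratio -0.18), the lower ones including endochitinase A (Os04g0494100, -3.77). Peroxidases and laccases had 8 of 69 lower and 2 higher, with peroxidase 27 (Os07g0531400) at an own ratio of -1.61, and a median of 0.05 that changed sign under 2 of 6 other scalings. WRKY factors had 4 of 51 lower (median -0.60, own ratio -0.23), including WRKY19 (Os05g0571200, -3.16). Other low genes were WSI76 of water stress (Os03g0316200, -5.27), alternative oxidase of mitochondria (Os04g0600300, -5.14) and a chalcone synthase family gene (Os02g0205500, -5.10), with vector ratios of 2.68, 2.91 and 3.10. MYB factors had 6 of 120 higher and 7 lower (median -0.11, own ratio -0.15), and ethanol and low oxygen genes 2 of 42 in each direction. Flavonoid genes had 3 of 31 higher and 2 lower (median -0.155, own ratio 0.007). Photosynthesis genes had 2 of 35 higher, and Os12g0240900 was the single call, higher, among 6 diterpenoid phytoalexin genes (median -0.34, own ratio -0.57). The diterpenoid median became 0.27 with both channels required above background and -1.98 with the software's processed signals. Storage genes had 3 of 28 lower (median -0.28, own ratio -0.09), jasmonate genes 1 of 25 and amylase and amide genes 1 of 17. The last is a glutamate decarboxylase (Os03g0236200, -3.51), not an amylase. No ribosomal protein gene of 300 was called (median 0.44, above every random list, own ratio 0.01). By own ratio this control list lay at percentiles 100, 0 and 83.4 of random lists in MYB30, MYB55 and MYB110. The phenylpropanoid entry and shikimate lists lay at 100 in each. With the software's processed signals 41.4% of calls were higher against 53.4%, and 33.4% with median centring, all in the direction of the labels. By own ratios alone 779 genes were higher and 689 lower, counts that a turn of the dyes would exchange. The 616 higher calls are fewer than the 996.8 of the simulated arrays, and the 537 lower calls more than their 479.9. The robust SD was 0.33 here against 0.44 in the vector array that the simulation used, so this decides nothing.

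**Figure D1:**
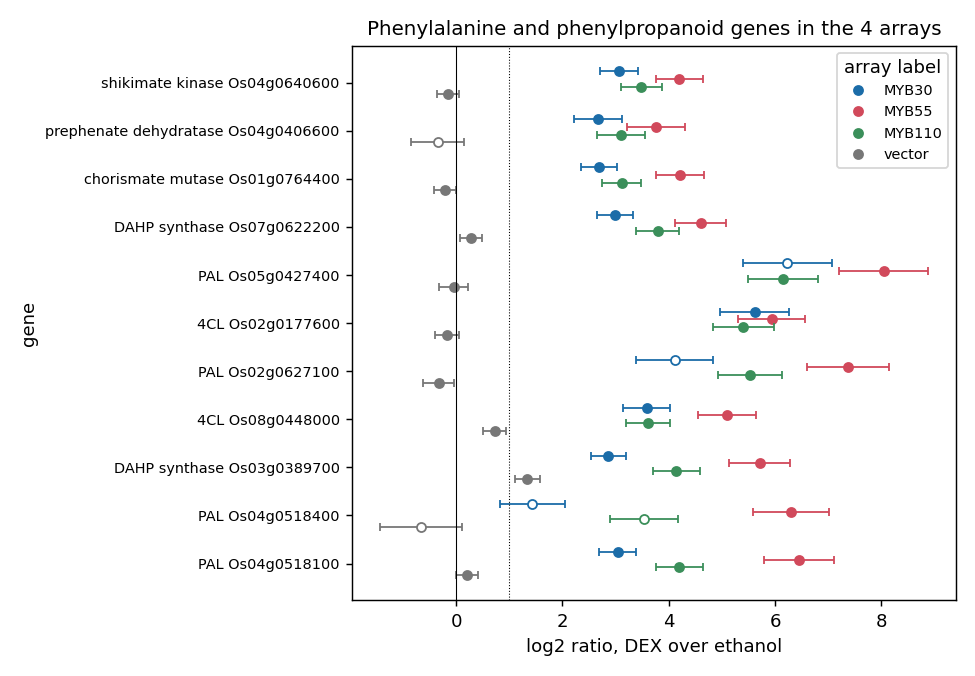
Each point is the log2 ratio of DEX over ethanol of one gene (vertical axis) in one array, coloured by its label. Bars are the software's technical error of its own ratio, and the dotted line is at 1. Open points have 1 channel not well above background and are fitted values, not measured sizes. In the vector array PAL gene Os05g0427400 had a ratio of -0.04, against 8.04 and 6.15 in the arrays labelled MYB55 and MYB110 and a bound of at least 61.0-fold in MYB30.

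Genes called in all 3 MYB arrays included several phenylpropanoid genes. Of the 184 called higher in all 3, the 10 ranked first by the smallest of their 3 differences included PAL (Os05g0427400 and, by its brightest probe, Os02g0627100), 4CL (Os02g0177600), both methyltransferases (Os08g0498100, Os08g0157500), JIOsPR10 (Os03g0300400), fasciclin domain gene Os05g0563600 and an ethylene response factor (Os01g0657400, 4.11, 4.75 and 3.85). Second probes gave smaller differences, of 2.35, 2.84 and 2.19 for Os01g0657400 and 1.86, 2.2 and 2.15 for Os05g0563600. Both were dim in the DEX channel of the vector array. The other 2 of the 10 are Os03g0216900 and Os03g0817800, which have no described function. Genes called lower in all 3 numbered 7, against 57 with the software's processed signals and 56 with median centring.

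Among 21578 genes measured on every array, 178 were higher in all 3, against 0.60 for independent lists and a mean of 3.90, at most 10, in the simulated arrays. The arrays labelled MYB55 and MYB110 shared 427 higher genes, against 34.7 for independent lists and a simulated mean of 59.4. MYB30 shared 202 with MYB55 and 232 with MYB110, against 22.3 and 9.92 for independent lists. Shared lower genes numbered 9, 55 and 51 for MYB30 with MYB55, MYB30 with MYB110 and MYB55 with MYB110. The simulated mean of 14.5 exceeded the first of these. Differences from the vector array correlated across genes at r = 0.62, 0.84 and 0.75 for these pairs, where simulation gave 0.50, and genes are not independent replicates. The covariances were 0.38, 0.54 and 0.57 against a simulated 0.38. Own ratios, which do not use the vector array, correlated at 0.38, 0.58 and 0.55, and with the vector array at 0.15, 0.19 and -0.16. By own ratios alone, without the vector array, 271 genes were higher and 17 lower in all 3 MYB arrays, against 184 and 7 by the full rule. Shared calls thus do not need the vector array, but own ratios keep any effect of DEX or dye bias. In the full rule the vector array enters all 3 comparisons and could not be split.

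**Figure D2:**
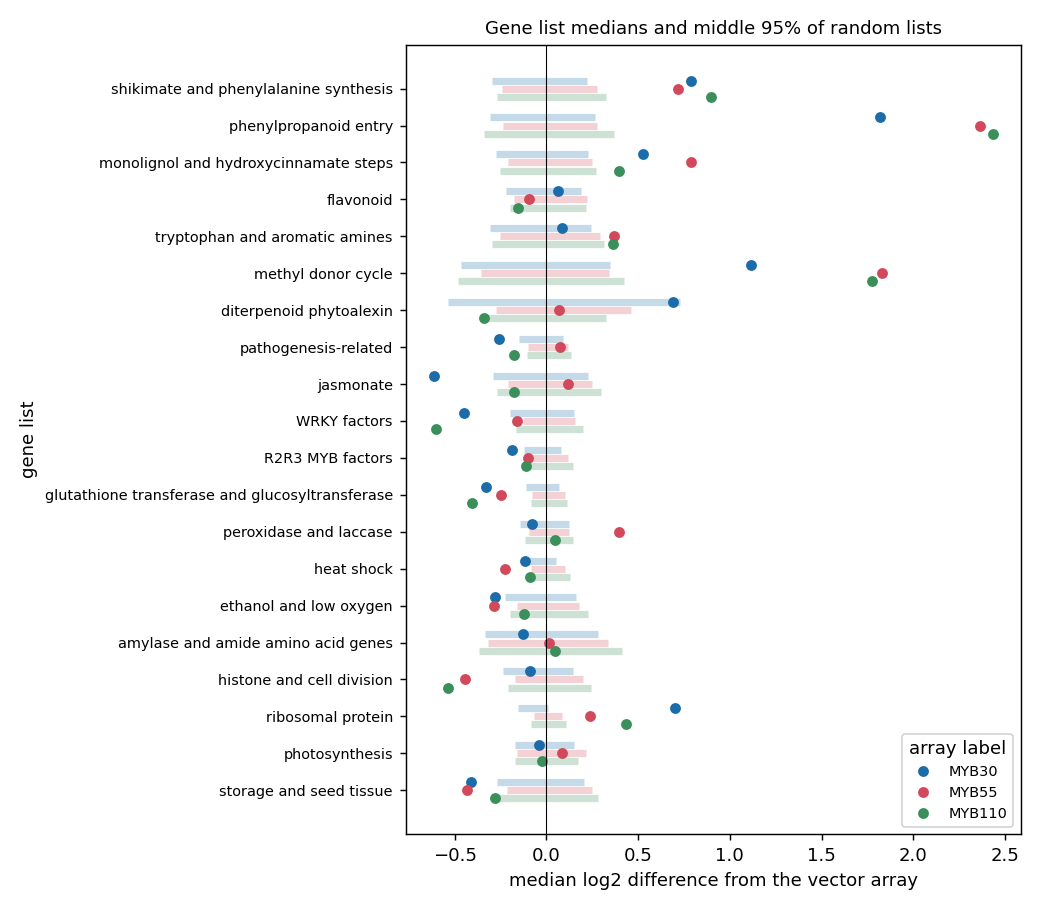
Points show the median log2 difference from the vector array (horizontal axis) of each of 20 gene lists in the 3 MYB arrays, and pale bars the middle 95% of matched random lists. Phenylpropanoid entry genes lie at 1.82, 2.36 and 2.43, and ribosomal protein genes, the control list, at 0.70, 0.24 and 0.44.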

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

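All of these results were singled out only after they were seen, by rules fixed earlier. Among genes called in opposite directions in 2 MYB arrays, 4 stood apart by the size of the gap, and the difference between arrays was not tested. Os03g0206400 differed from the vector array by -1.14 in the array labelled MYB30 and by 4.09 in MYB55. Os05g0203500 had 1.32 in MYB30 and -3.62 in MYB110. Os04g0268700 had -2.11 in MYB30, 2.49 in MYB55 and -1.70 in MYB110. Os04g0659300 had 2.41 in MYB55 and -1.88 in MYB110. Os04g0268700 is described as an eggshell protein family member and Os04g0659300 by a DUF26 domain, and the others as conserved hypothetical proteins. Second probes of Os03g0206400 (-1.06 and 4.01 in MYB30 and MYB55) and Os04g0659300 (2.23 and -1.78 in MYB55 and MYB110) gave like differences.

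Probes without a locus, which no comparison used, include microRNA probes. By the size rule 1 was called in the array labelled MYB30 and 3 in MYB110, of 173 and 171 measured, and none in MYB55. Named after their values were seen, a probe for osa-miR156b had a difference from the vector array of 1.71 in MYB30 and 2.97 in MYB110. A second osa-miR156b probe had 2.45 and one for osa-miR169i -1.35 in MYB110.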

How the results depend on the processing

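The limit to genes measured in the vector array and the use of bounds for dim channels were chosen only after the result was seen. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Of the comparisons of a count or an MYB ratio with its value under another setting, 199 stayed within 1.5 times the count or within the software error and 48 did not. List medians changed sign in 39 comparisons, of which 7 concern a median outside the middle 95% of random lists and 32 a median inside it. Leaving out those 7, 555 medians stayed within their spread and 217 moved. For single genes 2026 values stayed within the software error and 364 moved. Values changed sign in 8 comparisons, none of a called gene and all with the own ratio only. Phenylalanine, shikimate and phenylpropanoid lists kept positive medians in all 3 MYB arrays under all 6 other scalings. These 6 are not all distinct checks. Aquantile scaling leaves the ratio of a probe unchanged, and the deposited table nearly repeats the software's processed signals.

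With the software's processed signals the vector array had 2014 higher and 2379 lower calls, MYB30 697 and 494, MYB110 948 and 1340, and MYB55 1062 lower. Genes called in all 3 MYB arrays numbered 288 higher and 57 lower, and the ratios of the MYB30 and MYB110 genes in their own arrays were 0.62 and -1.83. The deposited table gave the same vector, lower and shared counts and MYB ratios, with 696 higher for MYB30 and 947 for MYB110. Of the higher calls of the report, 400 of 409, 1352 of 1444 and 610 of 616 were also called with the processed signals. With median centring the vector array had 2972 lower calls, MYB30 330, MYB110 870, and MYB55 854 higher and 580 lower. Shared lower genes were 56, and the MYB30, MYB55 and MYB110 genes had ratios of 0.77, 1.18 and -1.80. Of the 1444 higher calls for MYB55 827 were also called. With a normexp offset of 10 lower calls were 1196 in the vector array and 348 in MYB55, and 16 were shared. The cause was not tested for these settings.

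A log2 threshold of 1.5 calls fewer genes by its construction, with 536 higher and 205 lower in the vector array, 188 and 24 in MYB30, 747 and 52 in MYB55, 294 and 145 in MYB110, and 95 and 0 shared. Using the own ratio only removes a criterion, and gave 343 lower in MYB30, 503 in MYB55 and 17 shared. It also turned the sign of 12 list medians. Among medians outside the middle 95% of random lists these were 4, all in MYB55, which became 0.065 for WRKY factors, 0.066 for MYB factors, 0.004 for ethanol and low oxygen genes and -0.206 for ribosomal proteins. These 4 directions rest on the vector array. Requiring both channels above background left 6 phenylpropanoid entry genes in MYB30 and turned the diterpenoid median in MYB110 to 0.267. Without a filter on dim probes the storage median in MYB55 was 0.007, while no count changed, since no gene dim in both channels reached the threshold. Median centring turned the heat shock median in MYB110 to 0.055. The cause of these turns was not tested. Other probes of called genes passed the rule in 239 of 312 cases in MYB30, 691 of 897 in MYB55 and 464 of 621 in MYB110. Signal over background limits ratios with 1 dim channel to bounds, as for 32, 94 and 26 higher calls in MYB30, MYB55 and MYB110 with a dim ethanol channel.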

Other observations

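All tests of this part except that on dim probes were chosen only after the result was seen.

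Some genes passed a log2 ratio of 1 in the same direction in all 4 arrays, the vector array included. They numbered 52 higher and 7 lower of 21578, where independent lists would give 0.091 and 0.0074. Named after their values were seen, a LysM domain gene (Os10g0524300) had 4.11, 4.09, 4.03 and 3.75 in MYB30, MYB55, MYB110 and the vector array, and a NAM domain gene (Os01g0862800) had 3.19, 2.22, 2.25 and 3.11. The 52 also include DAHP synthase (Os03g0389700), a shikimate kinase (Os02g0749300), cinnamate 4-hydroxylase (Os02g0467600), PAL gene Os02g0626400 and a hydroxycinnamoyl transferase (Os02g0611800). Their vector ratios were 1.34, 1.255, 1.07, 1.03 and 1.33, each smaller than the gene's ratio in every MYB array. With no dye swap, an effect of DEX and a dye bias of the probes of all these genes were not separated.

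The vector array had 1337 higher and 679 lower calls without an MYB gene on its construct. Noise of dim probes would leave under 1% of the brightest genes called, but 10.7% were, against 8.75% of all measured genes. A dye bias of single probes shared by the arrays would repeat in the other arrays, but over the called genes r with MYB110 was -0.189, and with MYB30 and MYB55 0.224 and 0.284, across genes that are not independent replicates. Both are argued against as the whole cause. A stress or growth state differing between the DEX and ethanol calli may be involved, since 3 of 3 lists, for ribosomal proteins, WRKY factors and jasmonate, lay outside the middle 95% of random lists. These lists were picked with their values known, so this cannot decide, and DEX itself and handling cannot be told apart with 1 array.

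The MYB probes were not highest in their own arrays. Probes outside the transcribed part of the transgene could give this, and 0 of the 4 probes had a stop codon in all 3 forward frames, which leaves it open. With vector and construct arrays exchanged in the labels, the array labelled vector could hold higher phenylpropanoid entry genes, and 3 of 16 were called. The list's median own ratio was 0.25 there, against 2.00, 3.10 and 3.41 in the MYB arrays, which runs with the labels. All 3 MYB genes were high in the array labelled vector, where an exchange with 1 construct would account for 1 of them, so their probes give no ground for an exchange. Reading the list against an exchange assumes that the MYB proteins raise these genes, so it stays open. If the dyes of the MYB110 array had been turned in the labels, its phenylpropanoid entry genes would lie opposite to the other MYB arrays. Their median own ratio had the direction of the others. Across genes the own ratios of this array also ran with those of MYB30 and MYB55, at r = 0.58 and 0.55. Both count against a turn only if MYB110 acts in the same direction as the other proteins. The 52 higher and 7 lower genes past the threshold in all 4 arrays also ran as labelled, but dye bias was not separated for them. The ratios of this array ran against the vector array at r = -0.163, so a turn stays open. No biological explanation was tested.

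Higher calls outnumbered lower calls, at 73.5% of calls pooled over the MYB arrays in the direction of the labels. In MYB30 and MYB55, which do not rest on the direction of the MYB110 array, the shares were 75.5% and 86.7%. The background offset could shrink ratios more in the dimmer Cy3 channel and so lower the number of lower calls. With the offset at 10 in place of 50 the pooled share was 69.7%, and 72.7% and 82.9% in MYB30 and MYB55, which argues against the offset as the whole cause in the MYB arrays. In the vector array the share went from 66.3% to 57.5%, so there the offset may have a larger part. The processed signals gave 54.6% pooled, 58.5% and 63.4%, and median centring 47.2%, 47.8% and 59.6%, so the excess depends on the scaling, and which step sets it was not tested. No biological explanation was tested.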
